A study of Mus musculus with 16 samples.

How the data were processed

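Total RNA of 16 mouse samples was measured on 1-channel Affymetrix arrays, 1 array per sample. The samples formed 6 groups by their titles: 1 ES cell culture, and 3 arrays each of normal kidney, kidney tumor, secondary kidney tumor, normal liver and liver tumor. Per the labels' protocols, RNA was extracted with the RNeasy Plus Mini kit, fragmented enzymatically and biotinylated with the Affymetrix WT Terminal Labeling kit. The deposited values are linear intensities, 1 per probe set and array, and the authors' background correction, summarisation and normalization are not given in the sources used here. They ran from 20.7 to 20262, with array medians between 191 and 226, so the arrays had been brought to a similar level before deposit. No detection p accompanied the values, so a transcript near the low end could not be told from background and folds there are compressed. The cells sorted for early transgene expression and the DNA methylation data named in the series' design text were not analysed here.

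The log2 of each intensity was taken, with no further scaling. Of 28856 probe sets, the platform annotation of 2016 gave 1 gene symbol to 21789, several symbols to 1621 and none to 5446. Probe sets with 1 symbol were used, and of the 999 genes with more than 1 probe set the one with the highest mean over all arrays was kept, which left 19938 genes. No dim gene was removed. A probe cannot separate a transcript of an endogenous gene from one of an introduced reprogramming transgene where both hold its target sequence.

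Groups were compared with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 16 arrays, which left 10 residual degrees of freedom, and empirical Bayes moderation without trend (2.66 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, 2-sided. The 5 contrasts were kidney tumor against normal kidney, secondary kidney tumor against normal kidney, secondary against primary kidney tumor, liver tumor against normal liver, and the difference between the kidney and the liver tumor effect. Errors beside log2 changes are standard errors of that fit, and errors beside levels are SDs over 3 arrays. The fit takes 1 spread per gene over all groups, so its error is too small where a compared group varies more. Inmt, for example, had an SD of 1.74 in kidney tumors and 0.037 in normal kidney. The number of arrays limits the precision. The labels do not say whether the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

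There were 31 gene lists covering pluripotency and reprogramming, proliferation, fetal and imprinted genes, chromatin, signalling, metabolism and the cell types of the 2 organs and their surroundings. Of their 539 entries, 494 had a probe set; H19, for example, had none. All but the sex-linked list, 30 per contrast, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. With a correlation estimated from the data, none of these list calls held at an adjusted p under 0.05, and that value stands beside each list named. The fixed design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule named, per contrast, the 8 genes of largest fold in each direction whose arrays did not overlap between groups (5 for the difference between organs, without that demand), the 2 called members of largest fold from each list, and the reprogramming factors with Nanog, Lin28b and Igf2 throughout. Predicted gene models, receptor families and small RNAs were left out.

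Correlations of effects were computed across genes, with 100 simulations of unchanged groups where the contrasts shared control arrays. Genes high in ES cells were those at least 3 log2 units above the normal tissue of the other organ, so that the list shared no control array with the tumor effect. The steps were tested on simulated data of 19938 genes, of which 67, 67 and 66 had known log2 changes of 0.6, 1 and 2. At a true log2 change of 1, limma recovered 89.6% of 67 changed genes for kidney tumor against normal kidney, 88.1% for secondary tumor against normal kidney, 86.6% for secondary against primary tumor, 80.6% for liver tumor against normal liver and 65.7% for the difference between organs. At a true change of 2 these shares over 66 genes were 98.5%, 100%, 97%, 98.5% and 90.9%, and at 0.6 over 67 genes 61.2%, 62.7%, 50.7%, 56.7% and 19.4%. With so few changed genes the adjusted threshold is stricter than in the real contrasts, where many more genes were called. The shares are therefore not the power in the real data. The false calls numbered 8, 12, 12, 9 and 5.

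The alternatives were a fit on the compared groups alone, quantile normalization, centring each array on its median, leaving out the dimmest 33.3% of genes, averaging the probe sets of a gene, testing every probe set, an intensity trend with robust moderation, array weights, the title's number as a block, a demand of 2-fold, a test against 1.5-fold, and leaving out each array in turn. Lists were also tested with fry. After the data were seen, the 4 tumor arrays with Xist signal, and the 2 normal liver arrays with kidney transcripts, were left out as added alternatives, and the primary and secondary kidney tumor effects were also computed with separate normal kidney arrays.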

Results

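Gene expression was measured in tumors of mice in which reprogramming factors could be switched on with doxycycline. Per the series' design, mice received doxycycline from 4 weeks of age for 7 days, and kidney tumors were taken 7 days after it was withdrawn. Normal kidney of the same age and ES cells served as controls, and liver tumors and kidney tumors grown again under the skin of immunodeficient mice were profiled as well. The tumors came from chimeric mice and may hold cells of the host strain, per the labels. There were 3 arrays in each tissue group and 1 of ES cells, so no group was tested against ES cells. The ES cell array served as a reference for correlations and for choosing genes high in ES cells.

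The arrays separated by tissue and by tumor. The first principal component held 44.7% of the variance and the second 27.8%. Across genes, the mean correlation with the ES cell array was 0.792 ± 0.00102 (SD, n = 3) in normal kidney, 0.900 ± 0.0166 in kidney tumors, 0.879 ± 0.00153 in secondary kidney tumors, 0.769 ± 0.00775 in normal liver and 0.862 ± 0.00918 in liver tumors. In each of 4 comparisons, kidney tumor, secondary tumor and liver tumor against normal tissue and secondary against primary tumor, the groups did not overlap. The exact permutation p was 0.1 in each (2-sided, adjusted p 0.1 over the 4), the smallest that 3 arrays against 3 allow.

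**Figure D1:**
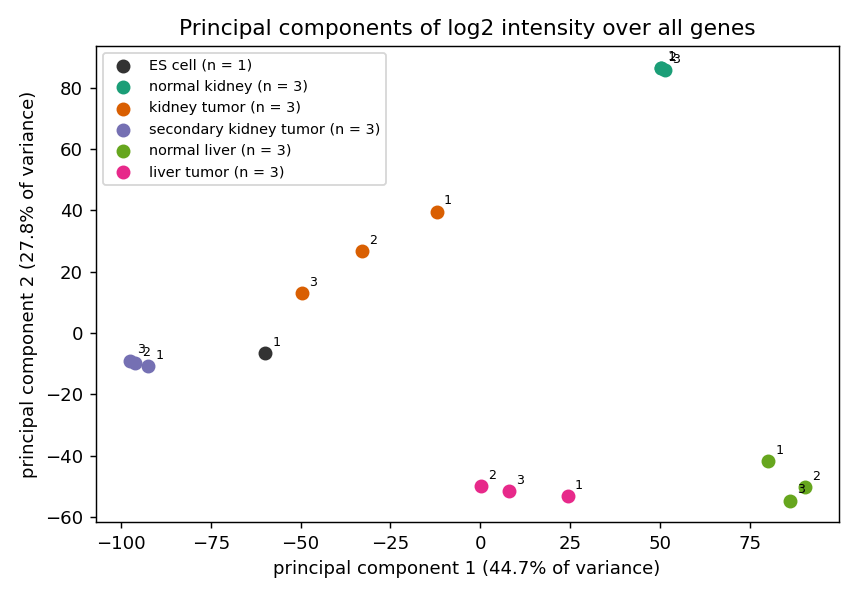
Principal components 1 (44.7% of variance) and 2 (27.8%) of log2 intensity over all genes, 1 point per array, coloured by group and numbered by replicate. The groups do not overlap, and the tumors of both organs lie between their normal tissue and the side of the ES cell array on component 1, with the secondary tumors beyond it.

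Kidney tumors were compared with normal kidney to show what had changed in the tissue after reprogramming was stopped. Trh, the thyrotropin-releasing hormone precursor (probe set 10546417), rose from 6.74 ± 0.25 to 12.52 ± 0.24 log2 units (SD, n = 3), a change of 5.79 ± 0.22 (SE). The glucose transporter gene Slc2a3 rose by 5.78 ± 0.19, the Nodal antagonist gene Cer1 by 5.69 ± 0.51 and the imprinted gene Peg10 by 5.47 ± 0.50. The retinoic acid binding protein gene Crabp1 rose by 5.29 ± 0.19 and Fndc3c1 by 5.50 ± 0.26. Inmt, a methyltransferase gene, fell (-5.85 ± 0.60), as did the solute carrier gene Slc22a30 (-5.11 ± 0.29), Azgp1 (-4.71 ± 0.29) and the brush border protease gene Mep1b (-4.38 ± 0.26). In limma, 9922 of 19938 genes were called, 4322 higher and 5600 lower, of which 1655 and 1602 changed at least 2-fold. The median change over all genes was -0.11. With each array centred on its median it was -0.24, and 3606 genes were higher and 8118 lower, so that the share of higher calls was 30.8% in place of 43.6%. Without the 2 tumor arrays with Xist signal, 5715 genes were called.

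Of the reprogramming factors, Sox2 rose by 4.46 ± 0.24 (SE, n = 3; adjusted p 5.1e-08 in limma), Pou5f1, which encodes Oct4, by 3.59 ± 0.42 (adjusted p 1.71e-05) and Myc by 2.07 ± 0.25 (adjusted p 1.97e-05). Klf4 stood at 7.91 ± 0.22 (SD) against 8.05 ± 0.10 in normal kidney, a difference of -0.14 ± 0.22 (SE) that did not pass (adjusted p 0.609). The list of 4 thus had 3 that rose, and 3 adjusted over the list alone (camera adjusted p 0.00737, adjusted p = 0.128 with an estimated correlation). Nanog, a core pluripotency factor, rose by 2.40 ± 0.27 and Lin28b, which blocks maturation of let-7 microRNAs, by 2.87 ± 0.19. Of 29 pluripotency genes, 14 rose, 2 fell and 13 did not pass, with the same counts adjusted over the list alone (median 0.50, camera adjusted p 0.00039, adjusted p = 0.367 with an estimated correlation). Sall4, a zinc finger factor of stem cells, rose by 4.11 ± 0.15. In the ES cell array Pou5f1 stood at 12.33, Sox2 at 11.92 and Nanog at 12.93, against 10.13 ± 0.33, 10.90 ± 0.56 and 9.67 ± 0.07 (SD, n = 3) in the kidney tumors.

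**Figure D2:**
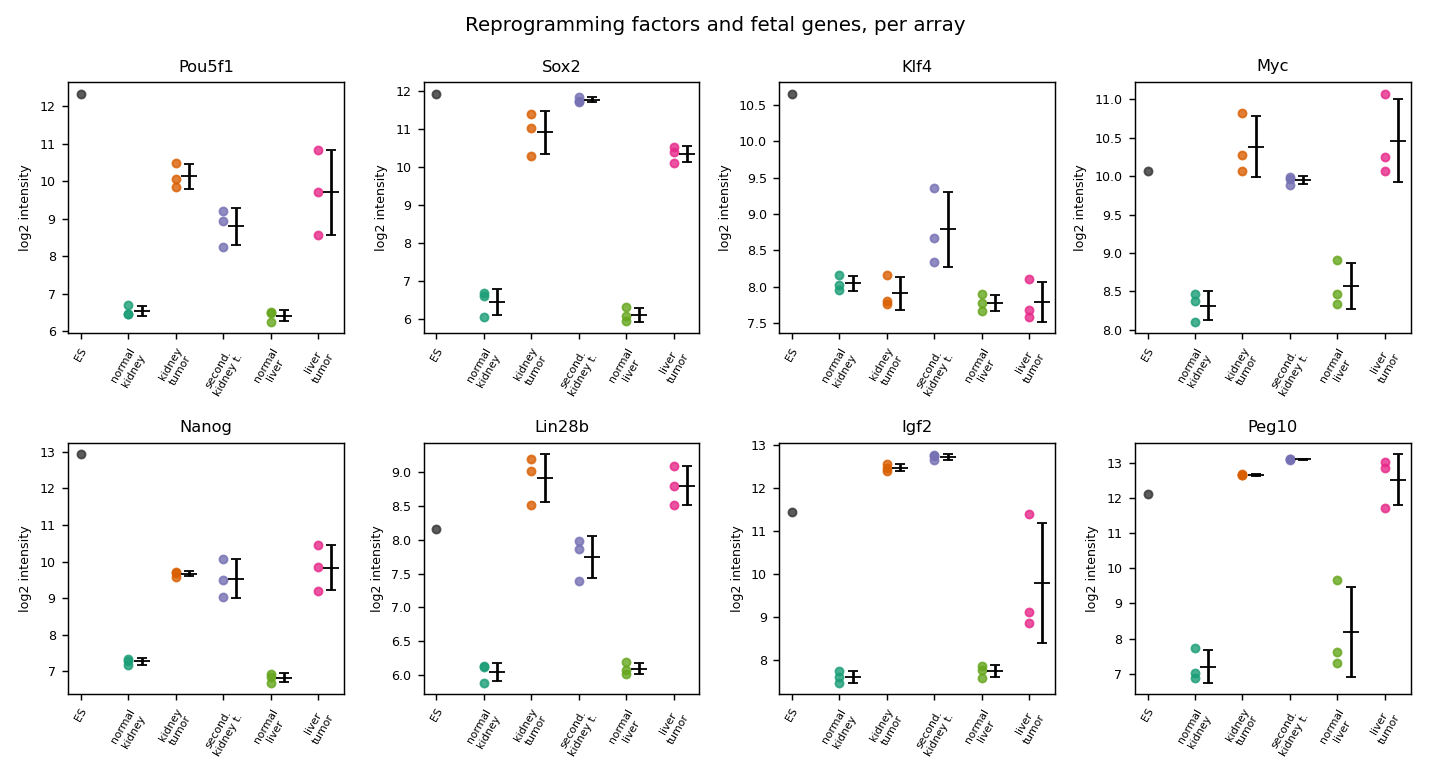
Log2 intensity of the 4 reprogramming factors, Nanog, Lin28b, Igf2 and Peg10, 1 point per array, with the mean and SD (bars) of each group of 3. Pou5f1, Sox2, Myc, Nanog and Lin28b are higher in the tumors of both organs than in normal tissue, and Klf4 is about 8 in normal tissue and primary tumors.

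All 39 cell cycle genes rose, and 39 adjusted over the list alone, by a median of 3.12 (camera adjusted p 4.92e-27, adjusted p = 0.169 with an estimated correlation); the checkpoint kinase gene Bub1 rose by 5.16 ± 0.29 and the topoisomerase gene Top2a by 4.70 ± 0.27 (SE, n = 3). Of 12 oncofetal genes 10 rose, and 10 adjusted over the list alone (median 3.57, camera adjusted p 4.47e-09, adjusted p = 0.128 with an estimated correlation). The fetal growth factor gene Igf2 (probe set 10569344) rose from 7.61 ± 0.13 to 12.46 ± 0.08 (SD), a change of 4.85 ± 0.46. Among 25 imprinted genes 22 rose and none fell; adjusted over the list alone 22 rose and 1 fell (median 1.61, camera adjusted p 2.31e-09, adjusted p = 0.128 with an estimated correlation). In the Polycomb and DNA methylation list 16 of 25 rose and 3 fell, 17 and 4 adjusted over the list alone (camera adjusted p 2.78e-06, adjusted p = 0.128 with an estimated correlation); the chromatin remodeller gene Hells rose by 3.85 ± 0.26 and the DNA methyltransferase gene Dnmt3b by 3.42 ± 0.30. In the hepatoblast and fetal liver list, which shares Igf2 and Peg10 with the lists above, 9 of 13 rose, and 9 adjusted over the list alone (camera adjusted p 1.29e-06, adjusted p = 0.169 with an estimated correlation). Of 21 germ layer and neural genes 17 rose, 18 adjusted over the list alone (camera adjusted p 8.32e-08, adjusted p = 0.128 with an estimated correlation), among them Eomes, a T-box factor of mesendoderm, by 3.81 ± 0.28. Of 11 Wnt targets 6 rose and 2 fell, also adjusted over the list alone (camera adjusted p 0.0116, adjusted p = 0.278 with an estimated correlation), with the antagonist gene Dkk1 up by 3.97 ± 0.24; the list's p was 0.064 without the dimmest genes.

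All 32 genes of oxidative phosphorylation fell, and 32 adjusted over the list alone, by a median of -0.80, or -0.93 with the arrays centred (camera adjusted p 4.69e-12, adjusted p = 0.152 with an estimated correlation); Sdhb, of complex II, fell by 1.24 ± 0.12 (SE, n = 3). Of 19 genes of fatty acid oxidation 18 fell, and 18 adjusted over the list alone (camera adjusted p 2.7e-06, adjusted p = 0.367 with an estimated correlation), with Acads, a short-chain acyl-CoA dehydrogenase gene, down by a log2 change of -1.78 ± 0.17. In the hypoxia and glycolysis list 6 of 17 rose and 2 fell, also adjusted over the list alone (camera adjusted p 0.0152, adjusted p = 0.431 with an estimated correlation), and the list lost its call without kidney tumor 1 (adjusted p 0.199) and without the dimmest genes (0.0899). The lactate transporter gene Slc16a3 rose by 3.56 ± 0.14 and the hexokinase gene Hk2 by 2.96 ± 0.22. Among proximal tubule genes 20 of 25 fell, 23 adjusted over the list alone (median -1.61, camera adjusted p 9.85e-06, adjusted p = 0.367 with an estimated correlation). Among genes of the loop of Henle and distal tubule 11 of 14 fell, 12 adjusted over the list alone (median -1.67, camera adjusted p 0.00039, adjusted p = 0.31 with an estimated correlation), and of the collecting duct 13 of 14, 14 adjusted over the list alone (median -1.80, camera adjusted p 1.61e-05, adjusted p = 0.31 with an estimated correlation). The calcium binding protein gene Calb1 changed by -2.35 ± 0.49 and the water channel gene Aqp3 by -2.47 ± 0.27.

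Several of the largest decreases differed among the tumor arrays. Slco1a1, an organic anion transporter gene, stood at 12.4 in each normal kidney array and at 9.82, 5.25 and 5.14 in kidney tumors 1, 2 and 3 (change -5.65 ± 0.91, SE), and Slc7a13, an amino acid transporter gene of the proximal tubule, at 10.35, 6.46 and 5.49 (change -5.59 ± 0.89). Xist, transcribed from the inactive X chromosome of female cells, stood at 5.60, 10.84 and 10.19 in the same 3 arrays and at 5.65 to 5.86 in normal kidney. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty was 9.42, 8.74 and 7.67 there, against 9.21 to 9.44 in normal kidney. Acsm3 (-4.97 ± 0.98) and Cyp2j13 (-4.57 ± 0.55) were further genes of large decrease.

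**Figure D3:**
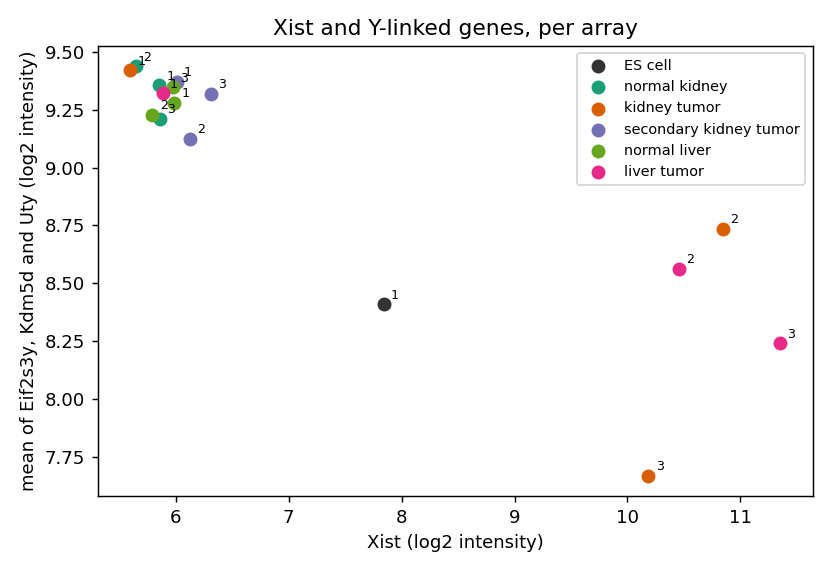
Xist against the mean of 3 Y-linked genes (both log2 intensity), 1 point per array, numbered by replicate. Kidney tumors 2 and 3 and liver tumors 2 and 3 lie at a Xist value of 10.19 or more with a Y-linked mean of 8.74 or less. The other arrays of tissue lie below 6.4 on the Xist axis. The ES cell array lies at a Xist value of 7.84 and a Y-linked mean of 8.41.

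Of 16 myeloid genes 13 rose and 1 fell in kidney tumors, also adjusted over the list alone (camera adjusted p 9.85e-06, adjusted p = 0.278 with an estimated correlation), led by the lipopolysaccharide co-receptor gene Cd14 at 3.43 ± 0.55 (SE, n = 3). Of 15 fibroblast and matrix genes 5 rose, but 3 adjusted over the list alone (camera adjusted p 0.00737, adjusted p = 0.514 with an estimated correlation), including the fibronectin gene Fn1 at 2.70 ± 0.19; without the tumor arrays with Xist signal the list's adjusted p was 0.186, and without the dimmest genes 0.052. The other 13 lists did not pass, with camera adjusted p between 0.122 and 0.885. Among them, of 22 nephron progenitor genes 8 rose and 4 fell, 8 and 5 adjusted over the list alone (adjusted p 0.322, adjusted p = 0.477 with an estimated correlation), with a median of -0.06 but a mean of 0.16 and an upward test; Eya1, a cofactor of early kidney development, rose by 2.77 ± 0.30. Of 13 p53 targets 5 rose and 3 fell, also adjusted over the list alone (adjusted p 0.297, adjusted p = 0.431 with an estimated correlation), and of 12 endothelial genes 6 fell, as adjusted over the list alone (adjusted p 0.122, adjusted p = 0.629 with an estimated correlation). Of 7 podocyte genes 5 fell and 2 rose, also adjusted over the list alone (adjusted p 0.252, adjusted p = 0.477 with an estimated correlation). The adipocyte list median was 10.24 in normal kidney 2 against 7.31 in both other normal kidney arrays, and 10.57 in normal liver 1 against 7.51 and 7.52 in normal liver 2 and 3.

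Secondary kidney tumors, grown from transplanted tumor, were compared with normal kidney and then with the primary tumors. Against normal kidney, 12 of 21 germ layer and neural genes rose and 2 fell, also adjusted over the list alone (camera adjusted p 0.000635, adjusted p = 0.251 with an estimated correlation). Kcnma1, a calcium-activated potassium channel gene, rose from 6.77 ± 0.18 to 13.45 ± 0.10 (SD, n = 3), a change of 6.68 ± 0.21 (SE). The microtubule regulator gene Stmn2 rose by 5.65 ± 0.76, the imprinted gene Nnat by 5.81 ± 0.59, the proteoglycan gene Vcan by 5.55 ± 0.37, the receptor phosphatase gene Ptprz1 by 5.50 ± 0.30 and the intermediate filament gene Ina by 5.46 ± 0.36. Ugt3a2, a glycosyltransferase gene, fell by 8.35 ± 0.30 to a level of 5.25 ± 0.20 (SD), and Kap, an androgen-regulated kidney protein gene, fell by 8.16 ± 0.73. In limma 13682 genes were called, 5962 higher and 7720 lower (2778 and 2216 at least 2-fold). The median change was -0.13, or -0.35 with centred arrays, which gave 4578 higher and 10774 lower, 29.8% higher in place of 43.6%.

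All 25 proximal tubule genes fell, and 25 adjusted over the list alone, by a median of -6.38 (camera adjusted p 5.1e-12, adjusted p = 0.234 with an estimated correlation). All 14 genes of the loop of Henle and distal tubule fell, as adjusted over the list alone (median -4.14, camera adjusted p 2.69e-06, adjusted p = 0.234 with an estimated correlation), and Umod, the uromodulin gene, fell by 7.00 ± 0.54 (SE, n = 3). Of 14 collecting duct genes 13 fell and 1 rose, also adjusted over the list alone (camera adjusted p 7.26e-06, adjusted p = 0.309 with an estimated correlation). Cell cycle genes rose in 38 of 39 cases, and 38 adjusted over the list alone (median 2.83, camera adjusted p 3.38e-16, adjusted p = 0.309 with an estimated correlation). Of 25 imprinted genes 21 rose and 2 fell, also adjusted over the list alone (camera adjusted p 2.69e-06, adjusted p = 0.234 with an estimated correlation), with Igf2 at 5.09 ± 0.46. All 4 reprogramming factors rose, and 4 adjusted over the list alone (camera adjusted p 0.0141, adjusted p = 0.234 with an estimated correlation): Sox2 by 5.33 ± 0.24, Pou5f1 by 2.26 ± 0.42, Myc by 1.63 ± 0.25 and Klf4 by 0.74 ± 0.22. All 32 genes of oxidative phosphorylation fell, as adjusted over the list alone (median -1.05, camera adjusted p 5.38e-12, adjusted p = 0.234 with an estimated correlation). Of 15 fibroblast and matrix genes 14 rose, as adjusted over the list alone (camera adjusted p 2.72e-05, adjusted p = 0.326 with an estimated correlation); Lum, a matrix proteoglycan gene, rose by 4.85 ± 0.52.

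Higher in the secondary than in the primary tumors was Cyp2f2, a cytochrome P450 gene of airway cells, by 5.70 ± 0.20 (SE, n = 3). It is not particular to airway cells here, with a mean of 12.505 in secondary tumors and 13.53 in normal liver. The antibacterial lectin gene Reg3g rose by 5.46 ± 0.16 and the keratin gene Krt4 by 4.84 ± 0.21. The astrocyte filament gene Gfap rose by 4.82 ± 0.13 and the airway secretory gene Bpifa1 by 4.76 ± 0.29. Gfap stood at 11.12 ± 0.26 (SD) against 6.31 ± 0.10. Slc13a1, a renal sulfate transporter gene, fell by 7.31 ± 0.42, and Umod fell by 6.29 ± 0.54. In limma 7168 genes were called, 3693 higher and 3475 lower (1488 and 870 at least 2-fold). The median change was -0.07, or -0.16 with centred arrays, which gave 3132 and 4921, 38.9% higher in place of 51.5%. Primary tumors 2 and 3 had Xist at 10.84 and 10.19 and Y-linked means of 8.74 and 7.67. All secondary tumors had Xist at 6.01 to 6.31 and Y-linked means of 9.13 to 9.37. This contrast was not run without the primary arrays with Xist signal, so the share of that difference in its calls is open.

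Of 9 keratinocyte genes 8 rose, as adjusted over the list alone (camera adjusted p 0.000111, adjusted p = 0.367 with an estimated correlation); Krt5, a basal keratin gene, rose by 4.39 ± 0.22 (SE, n = 3). Of 15 fibroblast and matrix genes 10 rose, 12 adjusted over the list alone (camera adjusted p 0.000175, adjusted p = 0.642 with an estimated correlation). Among proximal tubule genes 24 of 25 fell, 25 adjusted over the list alone (median -4.04, camera adjusted p 2.41e-17, adjusted p = 0.367 with an estimated correlation). Of 19 genes of fatty acid oxidation 15 fell, 16 adjusted over the list alone (camera adjusted p 1.38e-05, adjusted p = 0.642 with an estimated correlation), and the hypoxia response gene Ndrg1 fell by 3.43 ± 0.24. Of 39 cell cycle genes 3 fell and 36 did not pass, and 0 adjusted over the list alone (camera adjusted p 0.0637, adjusted p = 0.9 with an estimated correlation), and the list passed without primary tumor 1 (adjusted p 8.91e-05). Of 12 oncofetal genes 5 fell and 1 rose, 6 and 1 adjusted over the list alone (camera adjusted p 0.0445, adjusted p = 0.692 with an estimated correlation), with Lin28a at -1.99 ± 0.15 and Sall4 at -1.62 ± 0.15. The oncofetal call was lost without primary tumor 2 (adjusted p 0.0534) or 3 (0.0794) and without secondary tumor 3 (0.0537). It was also lost without the dimmest genes (0.0691) and with the replicate block (0.0551). Of 15 germline genes 6 rose and none fell, also adjusted over the list alone (camera adjusted p 0.0311, adjusted p = 0.692 with an estimated correlation), with Mael at 2.13 ± 0.25. The germline p was 0.058 without primary tumor 3 and 0.0712 without secondary tumor 2. Of 29 pluripotency genes 6 rose and 7 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p 0.704, adjusted p = 0.9 with an estimated correlation). Of 25 Polycomb and DNA methylation genes 5 rose and 2 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p 0.731, adjusted p = 0.9 with an estimated correlation); Dnmt3b fell by 2.02 ± 0.30. Dnmt3l rose by 0.75 ± 0.23 but lost its call without primary tumor 2 (adjusted p 0.0585) and without secondary tumor 2 (0.0866) or 3 (0.0702). Of the 4 reprogramming factors 2 rose and 1 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p 0.731, adjusted p = 0.9 with an estimated correlation). Sox2 rose by 0.86 ± 0.24 (adjusted p 0.0123, but 0.0518 in a fit on these 2 groups alone) and Klf4 by 0.88 ± 0.22. The difference of Myc, -0.44 ± 0.25, did not pass. Pou5f1 stood at 8.79 ± 0.49 (SD) against 10.13 ± 0.33, with an adjusted p of 0.0263 that was 0.05 without primary tumor 1, 0.0866 without primary tumor 3, 0.104 without secondary tumor 1 and 0.0502 without secondary tumor 3. None of the 12 skeletal muscle genes passed, also adjusted over the list alone, and the list did not (camera adjusted p 0.0706, adjusted p = 0.88 with an estimated correlation); its median was 10.80 in secondary tumor 1 and 6.93 and 6.92 in secondary tumors 2 and 3, and the adipocyte median was 9.87, 6.80 and 6.82. The muscle list passed without secondary tumor 2 (adjusted p 0.005) or 3 (0.00461).

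**Figure D4:**
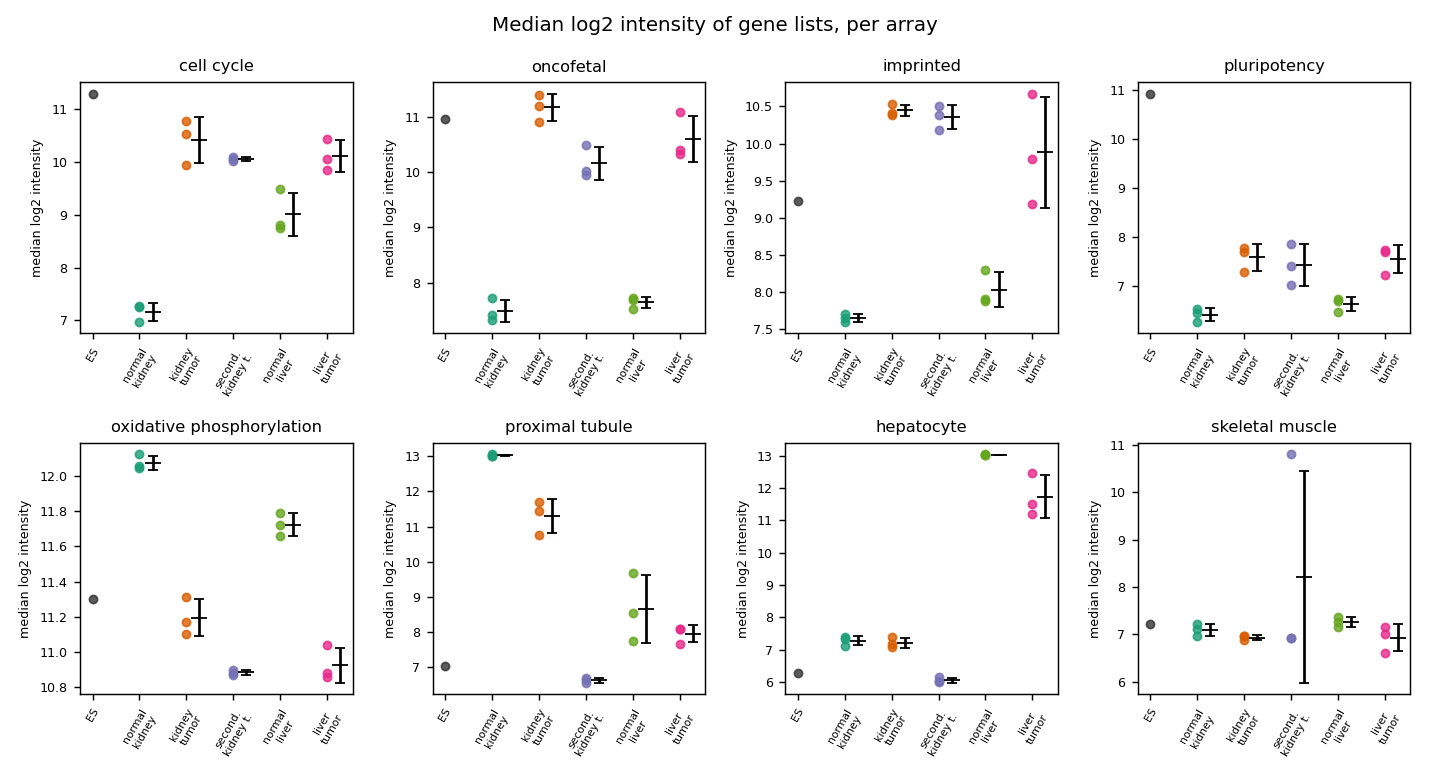
Median log2 intensity of 8 gene lists, 1 point per array, with the mean and SD (bars) of each group of 3; the vertical axes differ and do not start at 0. The proximal tubule median is 13.01 to 13.05 in normal kidney, 10.77 to 11.70 in kidney tumors and 6.56 to 6.70 in secondary tumors, and the skeletal muscle median stands apart in secondary tumor 1.

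The primary and secondary tumor effects correlated across genes with r 0.783 (Spearman 0.786) and covariance 0.828. Unchanged groups set against the same normal kidney arrays gave r 0.497 and covariance 0.0162 in 100 simulations. Both contrasts called 3499 genes higher, where independent lists would share 1292, and 4642 lower, where they would share 2168. With separate normal kidney arrays for each effect r was 0.756 to 0.773. This setting was chosen after the data were seen. The overlaps were counted with shared arrays, so the counts for independent lists are not what unchanged groups would give. Of the genes higher in primary tumors 50 were lower in secondary tumors, and of those lower 271 were higher.

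Liver tumors were compared with normal liver to show which changes arose in a second organ. Emb, a cell adhesion gene, rose by 5.66 ± 0.35 (SE, n = 3), Fndc3c1 by 4.92 ± 0.26, Slc2a3 by 4.83 ± 0.19, Crabp1 by 4.51 ± 0.19, and the embryonic transcription factor genes Otx2 and Zic2 by 4.65 ± 0.29 and 4.53 ± 0.21. Hsd3b5, a hydroxysteroid dehydrogenase gene of male liver (probe set values 11.58 ± 0.72, SD, in normal liver and 5.62 ± 0.45 in tumors), fell by 5.97 ± 0.30. The fatty acid elongase gene Elovl3 (-5.63 ± 0.46) and the cytochrome P450 genes Cyp4a12a (-5.83 ± 0.70) and Cyp2c55 (-5.01 ± 0.14) fell too. In limma 10419 genes were called, 4296 higher and 6123 lower (1431 and 990 at least 2-fold). The median change was -0.13, or -0.33 with centred arrays, which gave 3141 higher and 10389 lower, 23.2% higher in place of 41.2%. Without the tumor arrays with Xist signal 5862 genes were called, and without the normal liver arrays with kidney transcripts 6249.

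Sox2 rose by 4.23 ± 0.24 in liver tumors (SE, n = 3), Pou5f1 by 3.29 ± 0.42 and Myc by 1.89 ± 0.25, while the difference of Klf4, 0.01 ± 0.22, did not pass. That made 3 of 4 reprogramming factors, and 3 adjusted over the list alone (camera adjusted p 0.00501, adjusted p = 0.125 with an estimated correlation). Nanog rose by 3.02 ± 0.27. Of 29 pluripotency genes 11 rose and 3 fell, also adjusted over the list alone (camera adjusted p 0.0166, adjusted p = 0.584 with an estimated correlation); the list's median was 0.06, and turned to -0.03 with quantile normalization and -0.14 with centred arrays. All 12 oncofetal genes rose, as adjusted over the list alone (median 2.77, camera adjusted p 1.4e-09, adjusted p = 0.125 with an estimated correlation), with the fetal RNA binding protein gene Igf2bp1 at 4.28 ± 0.19 and Lin28b at 2.71 ± 0.19. Of 25 imprinted genes 16 rose and 1 fell, 19 and 2 adjusted over the list alone (camera adjusted p 1.87e-07, adjusted p = 0.125 with an estimated correlation). Of 39 cell cycle genes 33 rose and 1 fell, 34 and 1 adjusted over the list alone (median 1.11, camera adjusted p 1.63e-11, adjusted p = 0.37 with an estimated correlation). In the Polycomb and DNA methylation list 16 of 25 rose and 3 fell, also adjusted over the list alone (camera adjusted p 1.65e-06, adjusted p = 0.125 with an estimated correlation), and Tet1, which oxidises methylcytosine, rose by 3.00 ± 0.18.

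Of 28 hepatocyte genes 19 fell, 20 adjusted over the list alone (median -1.10, camera adjusted p 9.02e-05, adjusted p = 0.37 with an estimated correlation); the bile acid hydroxylase gene Cyp8b1 fell by 2.64 ± 0.21 (SE, n = 3). All 32 genes of oxidative phosphorylation fell, as adjusted over the list alone (median -0.73, -0.93 with centred arrays, camera adjusted p 1.63e-11, adjusted p = 0.138 with an estimated correlation), as did 18 of 19 genes of fatty acid oxidation, also adjusted over the list alone (camera adjusted p 6.51e-07, adjusted p = 0.37 with an estimated correlation). Of 17 hypoxia and glycolysis genes 12 rose and 1 fell, 12 and 2 adjusted over the list alone (camera adjusted p 2.99e-05, adjusted p = 0.231 with an estimated correlation); Slc16a3 rose by 3.45 ± 0.14 and the glucose transporter gene Slc2a1 by 2.53 ± 0.13. Of 16 myeloid genes 10 rose, 11 adjusted over the list alone (camera adjusted p 0.000198, adjusted p = 0.37 with an estimated correlation). Xist stood at 5.89, 10.45 and 11.35 in liver tumors 1, 2 and 3, while Hsd3b5 stood at 5.43, 6.12 and 5.29 in those arrays and at 10.76 to 12.09 in normal liver. Of 25 proximal tubule genes 8 fell and 3 rose in liver tumors, 6 and 2 adjusted over the list alone (camera adjusted p 0.301, adjusted p = 0.912 with an estimated correlation), and the list's median was 9.68, 8.55 and 7.75 in normal liver 1, 2 and 3.

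The tumor effects of both organs resembled each other across genes. Their correlation was r 0.684 (Spearman 0.657) over 19938 genes, which are not independent replicates, and the contrasts shared no array. Both called 2944 genes higher, against 931.3 for independent lists, with 149 of the genes higher in kidney tumors lower in liver tumors. Both called 3273 lower, against 1720, with 240 of the genes lower in kidney tumors higher in liver tumors. Shared risers included Slc2a3, Crabp1, Fndc3c1, Sox2 and Peg10. Xist signal lay in tumors 2 and 3 of both organs (10.84 and 10.19 in kidney, 10.45 and 11.35 in liver) and in no normal array. The correlation and overlaps were not computed without these arrays, so their share in the resemblance is open. Whether kidney and liver tumors of the same number came from the same mice is not stated.

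The difference between the organs was tested directly. The rise of cell cycle genes was larger in kidney: 37 of 39 differed, 39 adjusted over the list alone, by a median of 1.99 (camera adjusted p 8.14e-26, adjusted p = 0.538 with an estimated correlation), and the cyclin gene Ccna2 by 3.15 ± 0.37 (SE, n = 3). The cell cycle median was 6.97 to 7.28 in normal kidney, 8.75 to 9.48 in normal liver and 9.84 to 10.77 in the tumors of both organs. The RNA binding protein gene Igf2bp3 differed by 3.03 ± 0.37, and Fn1 by 2.60 ± 0.27, both with the larger change in kidney. Both were already higher in normal liver (means 9.06 and 13.25) than in normal kidney (6.34 and 9.93). Their tumor levels were closer, at 10.88 and 12.63 in kidney and 10.56 and 13.35 in liver. Igf2 differed by 2.80 ± 0.65 (adjusted p 0.0106), but by 2.65 with an adjusted p of 0.08 without the normal liver arrays with kidney transcripts. For Sox2 (0.24 ± 0.34), Pou5f1 (0.30 ± 0.60), Myc (0.18 ± 0.35), Klf4 (-0.15 ± 0.30) and Nanog (-0.62 ± 0.39) the difference did not pass, nor for any of the 4 reprogramming factors adjusted over the list alone (camera adjusted p 0.953, adjusted p = 0.987 with an estimated correlation). In all 3350 genes differed, 1503 with a higher and 1847 with a lower change in kidney than in liver. Centred arrays gave 1794 and 1533. Without the tumor arrays with Xist signal 2218 genes differed, without the normal liver arrays with kidney transcripts 2168, and with array weights 5209.

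Of 28 hepatocyte genes the difference, kidney minus liver, was above 0 for 12 and below for 2, 15 and 2 adjusted over the list alone (median 1.19, camera adjusted p 0.000188, adjusted p = 0.538 with an estimated correlation). Elovl3 differed by 5.48 ± 0.65 (SE, n = 3) and Cyp2c55 by 4.92 ± 0.19. The hepatocyte median was 7.11 to 7.40 in normal kidney against 13.01 to 13.03 in normal liver. The collecting duct median was 7.14 to 7.54 in normal liver against 10.30 to 10.50 in normal kidney. This left less room for a fall in the organ where these genes were low. The difference was below 0 for 9 of 14 collecting duct genes, 12 adjusted over the list alone (median -1.50, camera adjusted p 2.49e-07, adjusted p = 0.538 with an estimated correlation), among them the water channel gene Aqp3 at -2.04 ± 0.39. It was below 0 for 7 of 25 proximal tubule genes, 11 adjusted over the list alone (median -1.25, camera adjusted p 3.51e-05, adjusted p = 0.538 with an estimated correlation), with p = 0.0716 in fry. It was below 0 for 5 of 14 genes of the loop of Henle and distal tubule, as adjusted over the list alone (camera adjusted p 0.000746, adjusted p = 0.538 with an estimated correlation); without the tumor arrays with Xist signal the adjusted p was 0.059. Of 12 endothelial genes 5 lay below 0, 6 adjusted over the list alone (median -1.04, camera adjusted p 0.000399, adjusted p = 0.538 with an estimated correlation). Of 21 germ layer and neural genes 5 lay above 0, as adjusted over the list alone (median 0.54, camera adjusted p 0.00119, adjusted p = 0.538 with an estimated correlation).

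Genes high in ES cells were followed in the tumors. Of 213 genes at least 3 log2 units higher in the ES cell array than in normal liver, 131 rose and 11 fell in kidney tumors, by a median of 1.10 (camera adjusted p 4.94e-21 over the 4 contrasts, adjusted p = 0.0593 with an estimated correlation). Cell cycle genes, which rose in kidney tumors, were not removed from these genes, and the value without them is not given here. With the genes chosen against normal kidney, whose arrays the tumor effect shares, the median was 2.56. In secondary kidney tumors against normal kidney 153 rose and 19 fell, by a median of 1.46 (camera adjusted p 6.67e-16, adjusted p = 0.0593 with an estimated correlation). Between secondary and primary tumors 48 rose and 41 fell (camera adjusted p 0.672, adjusted p = 0.9 with an estimated correlation). Of 317 genes at least 3 log2 units higher in the ES cell array than in normal kidney, 211 rose and 13 fell in liver tumors, by a median of 1.13 (camera adjusted p 2.25e-25, adjusted p = 0.0593 with an estimated correlation). None of the 4 passed with an estimated correlation.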

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

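Apart from the adrenal gland test and the counts of other splits of the arrays, the tests in this part were chosen only after the result was seen, and the settings without arrays with Xist signal or kidney transcripts were added then too.

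The tumor effect differed between kidney and liver, by limma's test of the difference itself, for 3350 genes. Among gene lists the median difference, kidney minus liver, was 1.99 for cell cycle, 0.54 for germ layer and neural differentiation and 1.19 for hepatocyte genes. It was -1.25 for proximal tubule, -1.18 for loop of Henle and distal tubule, -1.50 for collecting duct and -1.04 for endothelium. Each of these 7 lists passed camera at the preset correlation, and none with an estimated one (adjusted p 0.538 for each). Without the tumor arrays with Xist signal the loop of Henle list no longer passed (adjusted p 0.059). Of single genes, the difference was 7.12 for Cyp4a14, 5.63 for Hsd3b5, 5.48 for Elovl3, 4.92 for Cyp2c55 and 4.18 for Sult2a8. Cyp4a14 rose in kidney tumors (2.08) and fell in liver tumors (-5.04), and the other 4 fell in liver tumors and stood near the low end in kidney, at means of 5.01 to 6.17 in normal kidney. The difference was -5.12 for Slc7a13, -4.88 for Car4, -4.33 for Apela, -4.11 for Pzp and -4.11 for Slco1a1. Mean Car4 was 12.808 in normal kidney and 12.402 in kidney tumors, against 7.705 in normal liver and 12.183 in liver tumors. Mean Apela was 11.514 and 11.173, against 5.9997 and 9.9914, in the same order. For Car4 and Apela the difference thus came mainly from higher means in liver tumors. Slc7a13, Pzp and Slco1a1 had lower means in kidney tumors than in normal kidney (7.43 against 13.02, 7.49 against 11.75 and 6.74 against 12.39). The call for Slco1a1 was lost on leaving out any array but kidney tumor 1 or liver tumor 3 (adjusted p 0.0704 to 0.11), and that for Pzp without the normal liver arrays with kidney transcripts (adjusted p 0.0769). Of 100 drawn splits of the arrays within each organ, 9 gave as many genes as the real one, itself included. The highest other gave 13321. That highest split exchanged the tumor and normal names in 1 organ. The other 7 splits with as many genes also kept the tumor and normal arrays of 1 organ apart, so they hold that organ's tumor effect. The 81 that mixed both organs gave 0 genes at the threshold. They put tumor and normal arrays in 1 group, which widens the spread within groups. This count therefore cannot decide on chance, which is not excluded.

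Probe sets without a single gene symbol, 7067 in all, are outside the gene results; tested against normal tissue, 1180 of them were called higher in kidney tumors and 1025 in liver tumors.

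Xist was above 10 in 4 of the 6 primary tumor arrays and at 5.60 and 5.89 in the other 2. The female-biased gene Slc7a12 was at least 1.39 higher in kidney tumors 2 and 3 than in any normal kidney array or kidney tumor 1. It varied from 6.42 to 8.19 in normal kidney (SD 0.93). As 1 gene measured in whole tissue, it does not show which cells held Xist. Xist switched on in male cells of male animals is therefore not excluded. A sex difference as the whole of the kidney tumor effect is argued against. Of 3793 genes called at 2-fold or more from kidney tumors 2 and 3, 88.3% changed the same way in kidney tumor 1, by at least 1.5-fold. Among other genes the share was 11.5%. With separate normal kidney arrays for the calls and for kidney tumor 1 it was 85.5% to 85.8% of the called genes. Female cells in these samples remain a candidate explanation, since the lowest Y-linked mean in tumor arrays without Xist signal exceeded the highest in those with it by 0.586 (SD 0.115 in normal kidney). The ES cell array, with Xist at 7.84, had a Y-linked mean of 8.41. That lay below kidney tumor 2 (8.74) and liver tumor 2 (8.56) and above kidney tumor 3 (7.67) and liver tumor 3 (8.24). A lower Y-linked mean was thus also seen in this 1 culture, but its Xist value lay above those of tissue arrays without Xist signal (6.31 or less). Those tissue arrays had Y-linked means of 9.13 to 9.44. Among tissue arrays, the lower Y-linked means were seen only in the tumors with Xist signal. Cells of the host strain, which the labels say the chimeric tumors may hold, male cells in a female host, and Xist in male cells of liver tumors 2 and 3 were not tested, and part of the fall of sex-biased genes may come from a sex difference.

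Normal liver 1 held kidney transcripts, and normal liver 2 less of them. The liver tumor arrays were not screened. Kap stood at 9.33, 10.06 and 8.02 in liver tumors 1, 2 and 3, against 7.08 in normal liver 3. Their proximal tubule medians were 8.09, 8.10 and 7.67, against 7.75. For normal liver 2 the excess over normal liver 3 was a median of 0.853% of the normal kidney level for proximal tubule, 1.04% for loop of Henle and distal tubule and 1.43% for collecting duct genes. For normal liver 1 these shares were 4.19%, 4.37% and 2.07%. The highest of these over the lowest was 2.11, past the bound of 2 set for whole-kidney tissue, but a bootstrap over genes, added after that value was seen, ran from 1.35 to 4.76, so whole-kidney RNA and RNA of part of the kidney cannot be told apart. Adrenal tissue taken along is consistent with a median excess of 2.39 log2 units over 14 adrenal genes, of which 8 were over 1 unit higher and 1 stood over 8 in normal kidney. Cyp21a1 stood at 12.01, Cyp11b1 at 11.62 and Star at 11.34 in normal liver 1, and near 6 to 7 in the other normal liver arrays; its adipocyte median was 10.57, against 7.51 and 7.52 there.

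Kidney tubule transcripts were kept in part in primary kidney tumors and lost in secondary ones. Dilution of unchanged normal kidney by tumor cells alone would lower all such genes by 1 common amount in each array. Their interquartile range would then be under 0.5. The lowest range was 1.01 over 265 genes, just past the bound of 1 set against dilution, with a lower bootstrap bound of 0.779. Within 3 classes of brightness, with the secondary tumor level subtracted, the lowest range was 0.881. A normal kidney array against the others gave at most 0.224. The values 0.779 and 0.881 lie between the bounds of 0.5 and 1, so the test does not decide on dilution alone. Some normal kidney tissue left in the primary samples remains a candidate explanation, since each of the 3 tubule lists in each primary array lay at least 1.27 above its highest secondary tumor level; the podocyte list lay below it (7.66 to 8.02 against 8.43, and 8.39 to 8.77 in normal kidney). Tumor cells that keep some tubule expression were not tested and stay open.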

How the results depend on the processing

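The settings that leave out arrays with Xist signal or with kidney transcripts, or that separate the normal kidney arrays, and their tests were chosen only after the data were seen; all other settings were set beforehand. Depth in the sense of signal over background could not be assessed, as no detection value was used here. The counts of called genes stayed within 1.5 times, in the order kidney tumor, secondary tumor, secondary against primary, liver tumor and difference between organs, except as follows. A demand of 2-fold, which by construction removes smaller changes, gave 3257, 4994, 2358, 2421 and 1511, and a test against 1.5-fold gave 2983, 5186, 1892, 1883 and 589. Array weights, whose estimation stopped before full convergence, gave 5209 for the difference between organs. Without the tumor arrays with Xist signal the counts were 5715 for kidney, 5862 for liver and 2218 for the difference; without the normal liver arrays with kidney transcripts they were 6249 for liver and 2168 for the difference. These settings use fewer arrays, and other causes were not tested. Secondary against primary tumor was not run without the primary arrays with Xist signal. With 1 array left out the counts ranged from 8373 to 10040, 12251 to 13000, 5733 to 6642, 8575 to 10860 and 2534 to 4573; where 2 arrays of a group were left out, the lone array is assumed to vary like the other groups. The correlation of the kidney and liver effects was 0.697 over genes called in either, 0.702 without the dimmest genes, and 0.659 to 0.698 with 1 array left out. The median change of ES-high genes ranged from 1.01 to 1.29 in kidney tumors and from 0.989 to 1.35 in liver tumors with 1 array left out. With genes chosen against the same organ, whose control arrays the effect shares, it was 2.56 in kidney tumors and also higher in liver tumors, and without the dimmest genes it was 1.54 and 1.35. The correlation of the primary and secondary tumor effects, 0.783, was 0.770, 0.756 and 0.768 with normal kidney 1, 2 or 3 alone for the primary tumors and the others for the secondary, and 0.764, 0.768 and 0.773 the other way round. The number of lists passing, 69 over the contrasts (17, 19, 12, 14 and 7), was 0 in each with an estimated correlation; fry passed 23, 22, 14, 18 and 7. With 1 array left out the lists numbered 16 to 17, 18 to 20, 10 to 13, 14 to 17 and 7 to 9. The list fatty acid oxidation reversed in the difference between organs without the tumor arrays with Xist signal, from an adjusted p of 0.957 to 0.000573 in the opposite direction; the cause was not tested. Over 346 results on named genes, 6173 of 6545 values kept direction and side of the threshold, 359 lost the call, 13 gained it and 0 reversed; over 150 list results 1685 of 1825 kept both, 91 lost it, 48 gained it and 1 reversed. The replicate numbers were not taken to pair the samples: the correlations of same-numbered deviations were 0.0615, 0.0464 and 0.0563 for normal kidney and kidney tumor, and 0.0367, 0.0828 and 0.139 for primary and secondary tumor, each array correlating best with its own number in both. They were -0.103, -0.163 and 0.150 for normal kidney and secondary tumor, and all 3 lay below 0 for liver. Whether secondary tumors came from the primary tumors of their number is not stated. With the replicate block the counts were 9797, 13551, 7016, 10246 and 3295, with 68 lists.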

Other observations

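The lists in the first 3 paragraphs and their tests were chosen only after the result was seen, apart from the counts of other splits of the arrays and the adrenal gland list, which was written before its genes were looked at.

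Secondary kidney tumors held transcripts of further differentiated tissues. Of 14 astrocyte and glia genes 11 rose against primary tumors and none fell, by a median of 1.48 (camera adjusted p 4.92e-06 over 20 tests, adjusted p = 0.0752 with an estimated correlation), and 12 rose and 2 fell against normal kidney (adjusted p 0.000565, adjusted p = 0.109 with an estimated correlation). Of 16 airway and mucosal genes 12 rose and 1 fell against primary tumors, by a median of 2.78 (adjusted p 3.88e-09, adjusted p = 0.0846 with an estimated correlation). With an estimated correlation none of the 20 tests of these and the next lists passed. In primary kidney tumors 3 glial genes rose and 4 fell, and 2 airway genes rose and 2 fell; neither list passed (adjusted p 0.949 and 0.878; adjusted p = 0.963 for both with an estimated correlation). Several members, Gfap, Reg3g, Krt4, Cyp2f2 and Bpifa1 among them, had been seen before the lists were written. The tests of these 2 lists therefore partly restate what was seen, and the lists were not tested without those members.

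All 8 male-biased kidney genes fell in kidney tumors, by a median of -4.04 (adjusted p 0.00165, adjusted p = 0.159 with an estimated correlation). The list's median was 10.69 in kidney tumor 1, without Xist signal, and 7.55 and 7.12 in kidney tumors 2 and 3, against 12.55 to 12.73 in normal kidney. All 8 fell in secondary tumors, whose Xist values were 6.01 to 6.31 (adjusted p 0.00165, adjusted p = 0.159 with an estimated correlation). Of 10 male-biased liver genes 7 fell in liver tumors, by a median of -1.87 (adjusted p 0.00369, adjusted p = 0.159 with an estimated correlation). This list's median was 6.98 in liver tumor 1, without Xist signal, and 7.355 and 6.86 in liver tumors 2 and 3. In normal liver it was 10.38 to 11.96, so the low level was not limited to arrays with Xist signal. The list of 14 adrenal genes did not pass in any of the 4 contrasts tested (adjusted p 0.219 in liver tumors, where 4 members fell, adjusted p = 0.929 with an estimated correlation).

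The pluripotency genes that rose may be those of the epiblast more than those of the naive state of ES cells. In kidney tumors all 18 epiblast genes rose, by a median of 2.66, while of 17 naive pluripotency genes 4 rose and 2 fell, with a median of -0.02. The difference of medians was 2.68 (permutation of list membership, p = 3e-05, 2-sided, 100000 permutations), where genes are not independent replicates. Among genes at 8 or below in normal kidney the medians were 3.37 for 14 epiblast genes and 0.11 for 12 naive genes. In liver tumors 16 epiblast genes rose and none fell, against 0 and 3 naive genes. The contrast was smaller in secondary kidney tumors than in primary ones. There 14 epiblast genes rose and none fell, by a median of 1.53, while 6 naive genes rose and 2 fell, with a median of 0.30. Of these lists 7 epiblast and 14 naive genes also stand in the lists fixed beforehand, and most naive values had been seen, so this stays a hypothesis.

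For the remaining contrasts, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with as many genes in each: 9922 for kidney tumor with 0 as the highest other, 13682 for secondary tumor with 0, 7168 for secondary against primary with 1 and 10419 for liver tumor with 13. Those counts are fits on all 16 arrays. The other splits put arrays of both tissues in 1 group, which widens the spread within groups. Their low counts therefore do not measure chance.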
